A study of Mus musculus with 37 samples.

How the data were processed

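Bulk RNA-seq was measured in 27 libraries and ATAC-seq in 10 samples of conventional dendritic cells from the mesenteric lymph nodes of mice aged 8 to 16 weeks (12 weeks for ATAC-seq). Per the labels' protocols, cells were gated as live CD11c-positive single cells negative for CD19, TCRb, B220 and NK1.1. RNA was isolated with the RNeasy Micro kit, amplified with the NuGEN Ovation RNA-Seq System V2 and made into libraries with the Ovation Ultralow V2 kit. ATAC-seq libraries were made with Nextera transposase. The labels give no sequencing batch or date.

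The authors deposited raw read counts per gene, summed over exons and condensed to 1 entry per gene by HOMER on the mm10 build, per the file headers. Each entry pairs a gene symbol with a RefSeq transcript identifier and coordinates. These counts are not normalised and carry no strand information, so overlapping, antisense and near-identical genes cannot be told apart, and counts over whole genes do not resolve deleted exons. For ATAC-seq the authors deposited a list of peaks per group, in which each peak has a signal value, a -log10 p-value, a -log10 q-value and a score, per the file headers' column order. The score was capped in every list, the names and the score column point to filtering by irreproducible discovery rate and removal of chromosome Y, and details of neither are stated. The submitters' processing notes also name STAR 2.6.0, RSEM 1.2.30, DESeq2, Trimmomatic, Bowtie2 2.3.4, Picard, SAMtools 1.7 and MACS2, and the builds NCBIM37 and GRCm38.p5, without tying each to a file. Every column of the deposited files was used or checked.

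Samples were grouped by their labels into 9 RNA groups of 3 libraries and 4 ATAC groups of 2 or 3 samples. The labels do not say whether replicates came from separate animals. Of 24940 genes, 12459 passed edgeR's filterByExpr and were tested. Counts were scaled by TMM, and a quasi-likelihood model of all 9 groups (18 residual degrees of freedom, common dispersion 0.808) was fitted in edgeR 4.0.16 under R 4.3.3. Comparisons were contrasts of that model, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. A log2 fold change is given with its standard error, and TMM-scaled CPM as the mean ± SD of 3 libraries. When a group had no read of a gene, a fold was bounded against a floor of 3 counts over that group's libraries. Without molecular identifiers, floors and intervals cover counting error only.

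The 12 planned comparisons, the lists and the rule for naming genes were written before the data were examined. The rule named Irf4 and Irf8 in every comparison, and up to 6 genes per direction with the greatest log2 fold change among those with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between replicates. It left out predicted gene models, pseudogenes, microRNAs, snoRNAs and receptor segments. It also named up to 4 members per gene list with the smallest adjusted p below the threshold, and the 6 smallest adjusted p-values of each interaction. From the named genes, those whose call held in most alternatives are described. A further 3 comparisons, beside the interaction with Irf8 under exchanged labels, were added after the values were seen: resident against migratory Irf4 knockout libraries, double knockout against cDC2 wt, and labelled migratory control against cDC1 wt.

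A set of 24 gene lists held 370 genes, of which 360 are in the table. These comprised 14 program lists (cDC1 core, cDC2 core, migratory and maturation program, MHC class I presentation, MHC class II presentation, cytokines and T cell co-signals, interferon-stimulated, pattern recognition, dendritic cell transcription factors, chemokines and migration receptors, proliferation, unfolded protein response, cholesterol synthesis and dissociation stress). The other 10 held markers of B cells, T cells, NK and innate lymphoid cells, plasmacytoid dendritic cells, monocytes and macrophages, granulocytes, plasma cells, stroma and endothelium, erythroid cells and intestinal epithelium. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, again with an estimated correlation), except plasma cells and erythroid cells, which had too few tested genes. A list's genes were also adjusted over the list alone.

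Lineage genes were defined from libraries outside the Irf8 comparison as differing between cDC2 flox and labelled migratory control cells by at least 1 on the log2 scale. A lineage position was computed per library as the mean log2 (CPM + 1) of the cDC2-high genes minus that of the cDC1-high genes, set to 0% at the mean of cDC1 wt and 100% at the mean of cDC2 wt. Positions were compared by 2-sided exact permutation tests over 20 splits, whose smallest possible p is 0.1. Overlapping peaks within a list were merged to regions, and regions sharing at least 1 bp between lists counted as shared. A region was assigned to a gene when it touched the gene body or the 10 kb upstream of it. Shares of regions carry 95% Wilson intervals, and region changes were set against expression changes by 2-sided Fisher's exact tests over 12454 genes with Benjamini-Hochberg adjustment. Signal values were not compared between lists because their scaling is not stated. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

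The alternatives were DESeq2 1.42.0 (Wald test), RLE size factors, no filter on low counts, a minimum of 10 CPM in 3 libraries, a log2 fold change of at least 1 in size asked of the called genes, counts without Malat1, a model of only the groups compared, a replicate block and each library left out in turn. For lineage results they were genes from cDC2 wt, a log2 fold change of at least 2, pseudocounts of 0.1 and 5, and genes of at least 10 CPM. Lineage gene counts were also taken without genes that differ between labelled migratory control and cDC1 wt. For regions they were a reciprocal overlap of 50%, the 53152 highest-ranked regions of each list, regions above the median signal, a window of 2 kb around the transcription start and a window of 50 kb. A model without the 12 Irf4-floxed libraries and a lineage count from ex-cDC1 and cDC1 wt fitted alone were added after the values were seen.

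The tests were checked on simulated counts with 200 changed genes per comparison. In ex-cDC1 against cDC1 wt, 50% of 8-fold and 24% of 4-fold changes were recovered among 12042 genes, with 0 false calls. The recovery of 8-fold changes was 48% in cDC2 wt against cDC1 wt, 58% in DKO against ex-cDC1, 60% in DKO against cDC1 wt and 56% in ex-cDC1 against cDC2 wt. It was 38% and 56% in the labelled migratory and resident Irf4 knockout comparisons, and 62% in labelled migratory against resident control. It was 2% in the interaction of Irf4 genotype with gate and 26% in that with Irf8. False calls were 4 of 34 in cDC2 wt against cDC1 wt, 2 of 18 in the interaction with Irf8, 1 of 3 in that with gate, and at most 3 among the 30 to 50 calls of each other comparison. Changes of 1.5-fold were recovered in at most 2% in each of these comparisons. Simulated lineage genes of 8-fold were recovered in 86%, with 6 false calls. Those were drawn above a CPM floor that the real lineage genes did not have, so the real recovery can be lower. None of the 27 pairs of replicates were copies of each other. No sample was left out.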

Results

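Gene expression was measured by bulk RNA-seq in 27 libraries of conventional dendritic cells, which carry antigen to T cells, sorted from mouse mesenteric lymph nodes, and open chromatin by ATAC-seq in 10 samples. The cDC1 subset bears the chemokine receptor Xcr1 and depends on the transcription factor Irf8, and the cDC2 subset bears Sirpa and CD11b (Itgam). The RNA libraries formed 9 groups of n = 3. In Xcr1-cre reporter mice, cDC1 wt were reporter-positive and cDC2 wt reporter-negative and CD11b-positive. In Xcr1-cre reporter mice with floxed Irf8, ex-cDC1 were the reporter-positive and cDC2 flox the reporter-negative, CD11b-positive cells. Double knockout (DKO) cells carried floxed Irf4 and Irf8 with Xcr1-cre and were gated as reporter-positive, although their strain label lists no reporter. In the Irf4 arm, cDC1 from floxed Irf4 mice with Xcr1-cre (Irf4 knockout) or without it (control) were labelled migratory (high MHC class II) or resident (low MHC class II).

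Total counts were 4955809 to 9656351 in cDC1 wt, 4970254 to 6716080 in cDC2 wt, 3492842 to 6498078 in ex-cDC1, 6180599 to 9704216 in cDC2 flox and 6934292 to 8703574 in DKO. They were 4841272 to 14296346 in the libraries labelled migratory Irf4 knockout, 2554743 to 9546820 in migratory control, 5337689 to 11471074 in resident Irf4 knockout and 1942846 to 11931885 in resident control. Between 9895 and 12978 genes had a read, and the nuclear RNA Malat1 took 6.44 to 34.52% of counts. The labels do not say that replicates came from separate animals, so p-values measure only the spread between samples, which may be technical. That spread is shared over all groups, although replicates were less alike in cDC1 wt and DKO than in the Irf4 arm. Genes are said to rise or fall where edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 12459 genes passed 0.05, and lists where camera's adjusted p passed 0.05. Over the 12 planned comparisons camera called 60 list changes, of which 40 held with an estimated correlation, and p-values of the others are given where they are described.

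The targeted genes were examined first, as counts over whole genes. Irf8 (mm10 chromosome 8, 120738639 to 120756692) averaged 231 ± 59.7 CPM in cDC1 wt, 42.7 ± 15.7 in cDC2 wt, 10.1 ± 9.28 in ex-cDC1, 30.8 ± 14.9 in cDC2 flox and 77.5 ± 49.3 in DKO. Irf4 (chromosome 13, 30749233 to 30766981) averaged 103 ± 59.1 CPM in cDC1 wt, 155 ± 34.8 in cDC2 wt, 263 ± 79.0 in ex-cDC1, 216 ± 65.4 in cDC2 flox and 483 ± 291 in DKO. In the Irf4 arm, Irf4 averaged 173 ± 53.7 CPM in the libraries labelled migratory control, 28.8 ± 9.73 in migratory Irf4 knockout, 26.9 ± 29 in resident control and 12.9 ± 12.2 in resident Irf4 knockout. Irf8 there averaged 164 ± 32.4, 575 ± 64.1, 152 ± 38.6 and 601 ± 85.0 CPM in the same order. The DKO libraries therefore held Irf4 counts, and the gene totals do not separate floxed exons from the rest. The X-inactivation RNA Xist averaged 104 ± 138 CPM in cDC1 wt and had 0 reads in DKO, against 9590 ± 1030 CPM in labelled migratory control.

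**Figure D1:**
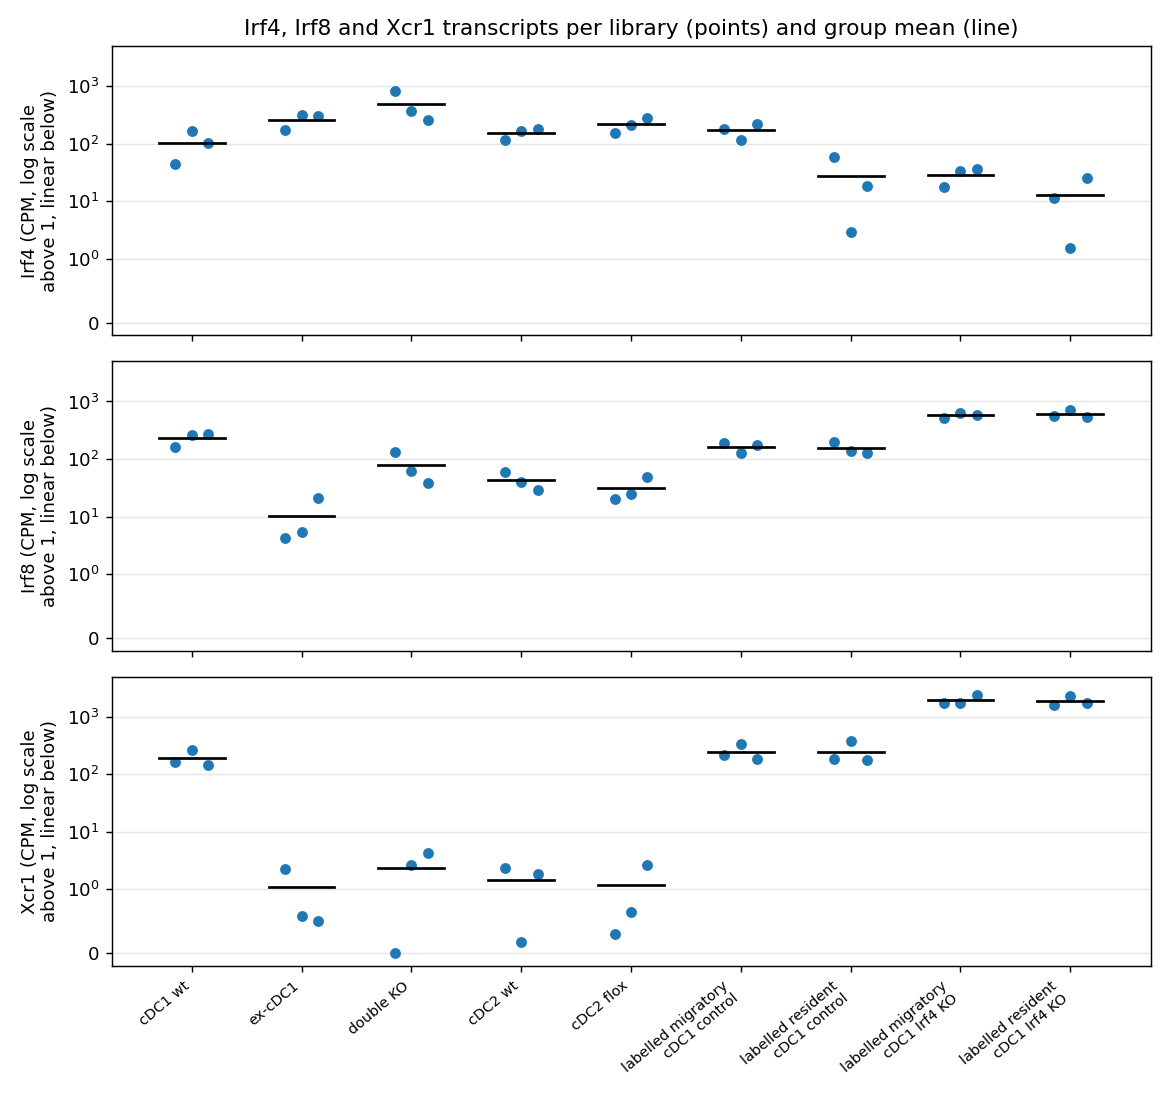
TMM-scaled CPM of Irf4, Irf8 and Xcr1 by group, on an axis that is logarithmic above 1 and linear below, with each point a library and a line at the mean of n = 3. Irf8 averaged 231 CPM in cDC1 wt and 10.1 CPM in ex-cDC1, and Xcr1 averaged 192 and 1.10 CPM in the same groups.

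The comparison of ex-cDC1 with cDC1 wt asked what cells with an Xcr1-cre history express when Irf8 is floxed. Irf8 fell by 4.49 ± 0.53 on the log2 scale (edgeR adjusted p = 2.85e-06). Xcr1, the receptor that defines cDC1, averaged 1.10 ± 0.968 CPM against 192 ± 66.3 (log2 fold change -7.36 ± 0.87, edgeR adjusted p = 1.41e-05). The co-receptor Cd8a averaged 0.057 ± 0.0986 CPM against 128 ± 15.6. The late endosomal GTPase Rab7b had 0 reads in ex-cDC1 against 27.3 ± 5.91 CPM and was at least 143-fold lower, and the surface glycoprotein gene Pianp was at least 371-fold lower. Rab7b was also lower in cDC2 flox than in cDC2 wt, as given below, so its fall cannot be separated from the strain. Il12b, a subunit of a T cell polarising cytokine, averaged 0.0982 ± 0.17 CPM against 64.7 ± 46.1. The oxysterol receptor Gpr183, which guides cDC2 positioning, rose by 5.55 ± 0.68 on the log2 scale to 245 ± 43.7 CPM (edgeR adjusted p = 6.31e-06). The transcription factor Prdm1 rose from 6.07 ± 5.26 to 124 ± 57.0 CPM (log2 fold change 4.37 ± 0.78, edgeR adjusted p = 0.00109). Tcte1 and Tmem151b, with 0 reads in cDC1 wt, were at least 151-fold and 157-fold higher. Irf4 averaged 263 against 103 CPM (log2 fold change 1.35 ± 0.71, edgeR adjusted p = 0.28, and 0.038 without the filter on low counts, in a range of 0.038 to 0.286 over the alternatives). In all, 464 genes changed, 208 higher and 256 lower in ex-cDC1. This count was 272, 259 and 255 without ex-cDC1 replicate 1, 2 and 3, and over processing settings it lay between 122 (only the 6 libraries) and 1379 (DESeq2).

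Among the fixed lists in this comparison, 9 of 20 cDC1 core genes fell, 0 rose and 11 did not pass (1 rose and 14 fell adjusted over the list alone, camera adjusted p = 1.67e-12). Members that fell included Xcr1 and the lysosomal thioesterase Ppt1 (log2 fold change -2.60 ± 0.36, edgeR adjusted p = 3.35e-05). Of 14 genes for MHC class II presentation, 6 rose, 0 fell and 8 did not pass (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0242, adjusted p = 0.386 with an estimated correlation). They included H2-Eb1, at 790 ± 119 against 301 ± 145 CPM, and its transactivator Ciita, at 313 ± 47.1 against 109 ± 26.3 CPM. Fitting only the 6 libraries ended both edgeR calls (adjusted p = 0.0642 and 0.072, the highest of ranges starting at 0.000152 and 0.000403 over the alternatives). Of 16 genes for MHC class I presentation, 3 fell, 0 rose and 13 did not pass (1 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.0242, adjusted p = 0.386 with an estimated correlation), among them the chaperone Pdia3 (log2 fold change -2.01 ± 0.43, edgeR adjusted p = 0.00523). The list of migratory and maturation genes did not pass (camera adjusted p = 0.0906). Its member Aldh1a2, which makes retinoic acid, fell from 1680 ± 341 to 271 ± 27 CPM, while the lipid-binding Apol7c rose from 2220 ± 465 to 4810 ± 288 CPM (edgeR adjusted p = 6.96e-05 and 0.00415). The interferon-induced chemokine Cxcl9 fell from 409 ± 265 to 38.4 ± 17.0 CPM (edgeR adjusted p = 0.000742).

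The other program lists did not pass in ex-cDC1 against cDC1 wt. Camera adjusted p was 0.115 for the cDC2 core and for pattern recognition, 0.749 for cytokines and for the unfolded protein response, 0.78 for interferon-stimulated genes, 0.499 for transcription factors, 0.816 for chemokines, 0.59 for proliferation, 0.0886 for cholesterol synthesis and 0.821 for dissociation stress. The lists of markers of other cell types did not pass either. Mean levels in ex-cDC1 and cDC1 wt were 38.8 and 7.45 CPM for B cells (camera adjusted p = 0.0886), 5.83 and 0.552 CPM for T cells (0.579), and 14.9 and 4.03 CPM for NK and innate lymphoid cells (0.78). They were 105 and 100 CPM for plasmacytoid dendritic cells (0.816), 21 and 43.9 CPM for monocytes and macrophages (0.0753), and 1.99 and 3.78 CPM for granulocytes (0.59). Stroma and endothelium averaged 10.5 and 166 CPM (0.0753) and intestinal epithelium 10.1 and 0.781 CPM (0.281). Plasma cell genes averaged 9.97 and 32.5 CPM and the erythroid gene 0 and 1.90 CPM, both untested by camera. The stroma mean rested on collagen, with Col1a1 at 879 ± 1260 CPM in cDC1 wt. Single markers did pass, among them Col1a1, which fell (log2 fold change -3.89, edgeR adjusted p = 0.00371). The endothelial marker Pecam1 and the epithelial marker Epcam rose (log2 fold change 9.59 and 6.46, edgeR adjusted p = 0.0373 and 0.0472). Median, mean and test direction differed in sign for the transcription factor, interferon-stimulated, chemokine and epithelium lists.

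Normal cDC2 were set against normal cDC1 in the same reporter mice. Xcr1 averaged 1.44 ± 1.12 CPM in cDC2 wt (log2 fold change -7.00 ± 0.84, edgeR adjusted p = 2.27e-05). Irf8 fell by 2.44 ± 0.48 on the log2 scale (edgeR adjusted p = 0.00267, and 0.0665 without the 12 Irf4-floxed libraries, the highest over the alternatives, from 1.23e-06). The collagen hydroxylase P3h2 averaged 0.0505 ± 0.0874 against 154 ± 81.6 CPM. Zeb2, a repressor in the cDC2 lineage, rose from 223 ± 172 to 1370 ± 240 CPM (log2 fold change 2.62 ± 0.50, edgeR adjusted p = 0.00244). Sirpa rose from 43 ± 28.8 to 380 ± 14.8 CPM (edgeR adjusted p = 0.0279). That call was lost without cDC1 wt replicate 1 or 3 (0.114 and 0.0828) and without cDC2 wt replicate 1, 2 or 3 (0.0672, 0.0692 and 0.0618). The cytokine Il1b rose from 30.9 ± 8.09 to 271 ± 53.2 CPM (edgeR adjusted p = 0.00427). The count of 507 changed genes, 250 higher and 257 lower, was 331 without cDC1 wt replicate 1, 227, 261 and 269 without cDC2 wt replicate 1, 2 and 3, 111 with only the 6 libraries and 1407 by DESeq2.

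In cDC2 wt, 10 of 20 cDC1 core genes fell, 0 rose and 10 did not pass (1 rose and 11 fell adjusted over the list alone, camera adjusted p = 4e-10). In the cDC2 core, 4 of 19 rose, 0 fell and 15 did not pass (6 rose and 0 fell adjusted over the list alone, camera adjusted p = 1.76e-10). For MHC class II presentation 7 of 14 rose, 0 fell and 7 did not pass (8 rose and 0 fell adjusted over the list alone, camera adjusted p = 4.76e-05), with H2-Ab1 at 3170 ± 457 against 1250 ± 472 CPM. The migratory list had 6 of 27 genes lower, 0 higher and 21 not passed (0 rose and 10 fell adjusted over the list alone, camera adjusted p = 1.51e-06), including Aldh1a2 (log2 fold change -2.58 ± 0.39, edgeR adjusted p = 0.000122) and the T cell chemoattractant Ccl5, at 265 ± 32.9 against 1080 ± 520 CPM. For pattern recognition 2 of 21 rose, 0 fell and 19 did not pass (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 3.65e-05), with the bacterial lipoprotein sensor Tlr1 at 278 ± 102 against 50.1 ± 27.9 CPM. Monocyte and macrophage markers averaged 89.4 CPM in cDC2 wt and 43.9 in cDC1 wt (camera adjusted p = 0.00113, adjusted p = 0.175 with an estimated correlation).

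Whether ex-cDC1 differed from cDC2 was tested against cDC2 wt and against cDC2 flox of the same strain. In ex-cDC1, 3 genes fell and 0 rose relative to cDC2 wt by edgeR, with 1258 at an unadjusted p under 0.05 (623 by chance) and 277 changed by DESeq2. These were Cd8a (0.057 ± 0.0986 against 40.7 ± 52.9 CPM, edgeR adjusted p = 0.0141), the protease gene Ece1 (19.2 ± 9.09 against 106 ± 69.1 CPM, edgeR adjusted p = 0.0244) and Rab7b (0 reads against 5.86 CPM, edgeR adjusted p = 0.00198), the last outside the naming rule and chosen after its values were seen. The Cd8a call was lost without ex-cDC1 replicate 1, 2 or 3 (0.201, 0.27 and 0.0679). The Ece1 call was lost without cDC2 wt replicate 1 or 2 (0.0507 and 0.262) and ex-cDC1 replicate 2 or 3 (0.39 and 0.0989). Fitting only the 6 libraries, or leaving out the 12 Irf4-floxed libraries, left 0 genes. The count was 5 without cDC2 wt replicate 3, 1 without ex-cDC1 replicate 2 and 7 without ex-cDC1 replicate 3. Irf8 averaged 10.1 against 42.7 CPM (edgeR adjusted p = 0.116, within 0.000419 to 0.723 over processing settings), a difference that passed without ex-cDC1 replicate 3 (0.00307), without the filter on low counts (0.000419) and by DESeq2 (0.00288).

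Against cDC2 flox, Irf2bp2, Slfn5 and Tns1 fell and Ttc39a rose in ex-cDC1 (each with an edgeR adjusted p = 0.0349). The adhesion scaffold Tns1 averaged 0.283 ± 0.26 against 66.3 ± 36.3 CPM, and Ttc39a averaged 262 ± 72.1 against 50.7 ± 30.7 CPM. The count of 4 was 0 without ex-cDC1 replicate 1 or 2, without cDC2 flox replicate 2 or 3 and without the 12 Irf4-floxed libraries, 8 without ex-cDC1 replicate 3, and 225 by DESeq2. Irf8 averaged 10.1 against 30.8 CPM (edgeR adjusted p = 0.349, and 0.0193 without ex-cDC1 replicate 3). Between cDC2 flox and cDC2 wt, Rab7b alone passed, at 0.0947 against 5.86 CPM (edgeR adjusted p = 0.00345, again chosen after its values were seen). That count was 0 without cDC2 flox replicate 2 or 3, 3 without cDC2 wt replicate 2, 0 with only the 6 libraries and 80 by DESeq2. Rab7b was thus low in both groups of the Irf8-floxed strain, ex-cDC1 and cDC2 flox.

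List tests nevertheless separated ex-cDC1 from both cDC2 groups. The cDC2 core averaged 67.1 CPM in ex-cDC1 against 150 in cDC2 wt and 157 in cDC2 flox (camera adjusted p = 1.26e-11 and 6.44e-11), with 0 of 19 genes passing singly, 3 lower against cDC2 wt and 4 lower against cDC2 flox adjusted over the list alone. Monocyte and macrophage markers averaged 21 CPM in ex-cDC1 against 89.4 and 118 (camera adjusted p = 7.6e-12 and 2.19e-12), with 0 of 12 genes passing singly and 2 lower in each comparison adjusted over the list alone. Migratory genes averaged 1050 CPM against 811 and 839 (camera adjusted p = 2.17e-05 and 8.79e-05), with 0 genes passing singly or adjusted over the list alone. The lectin genes Mgl2 and Cd209a, cDC2 surface markers, averaged 0.0982 and 4.65 CPM in ex-cDC1 against 10.8 and 53.1 CPM in cDC2 wt. The cDC1 core averaged 50.8 CPM in both ex-cDC1 and cDC2 wt (camera adjusted p = 0.114).

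To place cells between the lineages, 262 cDC1-high and 352 cDC2-high genes were taken from cDC2 flox and labelled migratory control cells. These groups came from different arms, so the genes may also hold differences of arm, strain or sex. Xist averaged 9590 ± 1030 CPM in labelled migratory control and 8.74 ± 5.84 CPM in cDC2 flox. The Y-linked gene Ddx3y averaged 53.3 ± 46.2 and 204 ± 42 CPM in the same order. In ex-cDC1 against cDC1 wt, 71 cDC1-high genes (27.1%) fell and 0 rose, while 63 cDC2-high genes (17.9%) rose and 3 fell. Among the other 11845 tested genes, 1.54% fell and 1.22% rose. Leaving out genes that differ between labelled migratory control and cDC1 wt, itself an arm of the test, kept 260 cDC1-high and 295 cDC2-high genes. Of these, 71 cDC1-high genes fell and 58 cDC2-high genes rose. Their median log2 fold changes were -1.23 and 0.99, against -1.23 and 0.72 with all lineage genes. The lineage position was not recomputed on the smaller sets. On a scale from cDC1 wt (0 ± 1.8%) to cDC2 wt (100 ± 4.8%), ex-cDC1 stood at 72.2 ± 8.7% and DKO at 79.5 ± 3.0% (SD, n = 3). The cDC1-high genes of ex-cDC1 had moved 97.6 ± 2.8% of the way and its cDC2-high genes 49.8 ± 17.0%. In DKO these parts were 105.5 ± 6.3% and 56.5 ± 5.1%. A 2-sided exact permutation test gave p = 0.1 for ex-cDC1 against either wild-type group, the smallest this design allows (0.12 after Benjamini-Hochberg adjustment over 6 tests), and p = 0.3 for DKO against ex-cDC1. The number of cDC2-high genes that rose was 39 without ex-cDC1 replicate 3 and 20 with both groups fitted alone, and the number of cDC1-high genes that fell was 40 with both groups fitted alone and 39 among genes of at least 2 on the log2 scale.

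**Figure D2:**
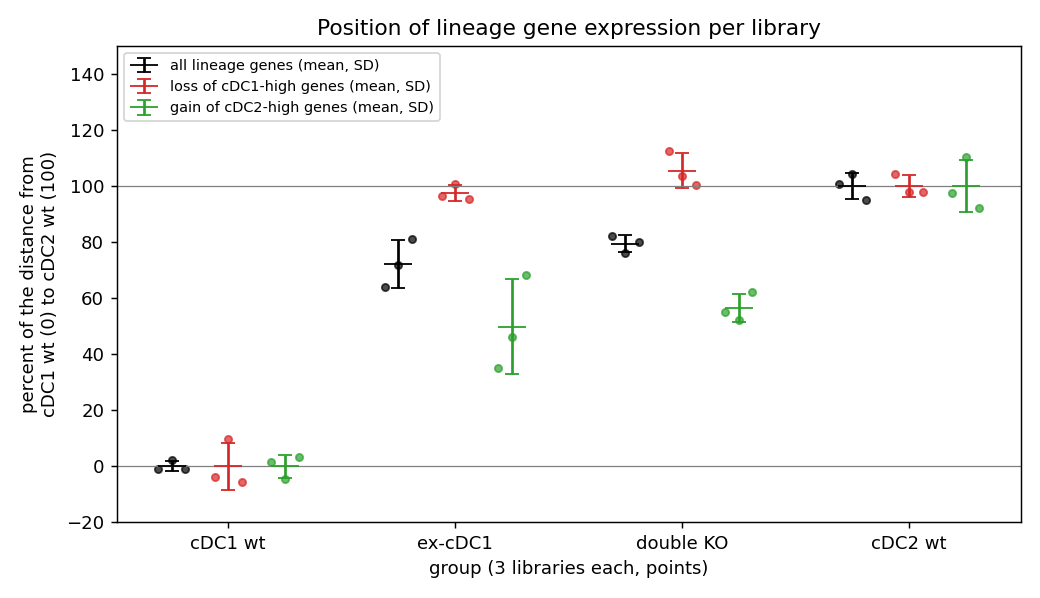
Lineage position in percent, from the mean of cDC1 wt at 0 to the mean of cDC2 wt at 100, with each point a library and bars at the mean and SD of n = 3. The ex-cDC1 libraries lay between 63.8 and 81.1% and the DKO libraries between 76.2 and 82.1%.

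Open chromatin was compared as lists of called regions, 1 list per group and so without replicates. Regions and genes are not independent replicates, so the intervals and tests below hold no spread between samples. There were 53152 regions in cDC1 wt, 67323 in cDC2 wt, 84814 in ex-cDC1 and 82077 in cDC2 flox, covering 33.7, 39.7, 50.2 and 48.9 Mb. Of 6779 regions called in cDC1 wt and not in cDC2 wt, 51.6% (95% interval 50.4 to 52.8) were called in ex-cDC1 and 47.2% (46.0 to 48.4) in cDC2 flox. Of 20342 regions called in cDC2 wt and not in cDC1 wt, 83.6% (83.1 to 84.1) were called in ex-cDC1 and 84.0% (83.5 to 84.5) in cDC2 flox. Both wild-type lists came from 2 samples and both Irf8-floxed lists from 3, so list length and genotype cannot be separated. With the 53152 highest-ranked regions of each list, the shares of cDC1 wt regions were 20.2% in ex-cDC1 and 16.5% in cDC2 flox, and those of cDC2 wt regions 71.9% and 77.1%. Genes that rose in ex-cDC1 more often carried a gained region, called in cDC2 wt and ex-cDC1 but not in cDC1 wt (53.8% against 38.6% of other genes, odds ratio 1.85, Fisher's exact test adjusted p = 2.2e-05). Genes that fell more often carried a lost region, called in cDC1 wt but not in ex-cDC1 or cDC2 wt (26.6% against 11.6%, odds ratio 2.77, Fisher's exact test adjusted p = 2.8e-10). They also more often carried a gained region (odds ratio 1.56, Fisher's exact test adjusted p = 0.000607), but within 2 kb of the start this odds ratio was 0.952 (adjusted p = 1, with a range of 0.0216 to 1 over the alternatives).

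**Figure D3:**
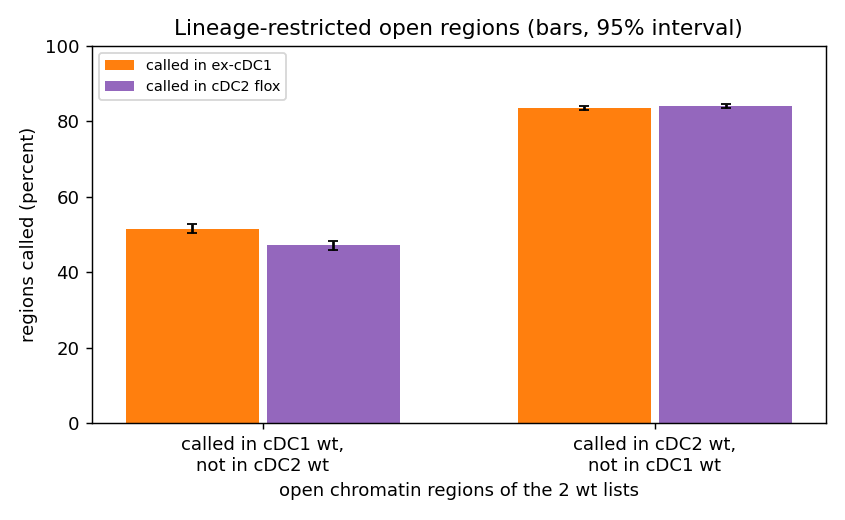
Percent of regions called in 1 wild-type list only that were also called in ex-cDC1 or cDC2 flox, with bars for shares and lines for 95% Wilson intervals. Regions of cDC2 wt were called in 83.6% and 84.0%, and regions of cDC1 wt in 51.6% and 47.2%.

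At the Irf8 locus 7 regions were called in cDC1 wt, 3 in cDC2 wt and 4 in both ex-cDC1 and cDC2 flox. Of 4 Irf8 regions called in cDC1 wt and not in cDC2 wt, 1 was called in ex-cDC1. The Xcr1 start region (chromosome 9, 123861868 to 123862249) was called in cDC1 wt only. The adhesion gene Cadm1 had 22 regions in cDC1 wt, 8 in cDC2 wt, 20 in ex-cDC1 and 17 in cDC2 flox, and 7 of its 14 regions absent from cDC2 wt were called in ex-cDC1. Clec9a, a receptor for dead cells, had 2, 4, 4 and 5 regions in the same order, and the cDC1 factor Batf3 had 4, 4, 5 and 5. Among cDC2 loci, Irf4 had 3, 6, 6 and 6 regions, Sirpa 3, 8, 6 and 8, Itgam 3, 6, 10 and 10, Zeb2 7, 11, 12 and 18, and Klf4 2 in each list. Mgl2 had 0, 3, 2 and 2 regions and Cd209a 0, 2, 3 and 3, with the RNA levels in ex-cDC1 given above.

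Cells with both Irf4 and Irf8 floxed (DKO) were set against ex-cDC1, in which Irf8 alone was floxed. The DKO libraries stood apart in the ribosomal entry Rn45s, which took 1.38% of counts against 0.399% in ex-cDC1 and 0.34 to 0.691% over the other group means, and Malat1 took 8.72% against 17.8%. Irf4 averaged 483 ± 291 against 263 ± 79.0 CPM (log2 fold change 0.88 ± 0.70, edgeR adjusted p = 0.485). Irf8 rose from 10.1 ± 9.28 to 77.5 ± 49.3 CPM (log2 fold change 2.92 ± 0.49, edgeR adjusted p = 0.000984, and 0.207 with only the 6 libraries, the highest over the alternatives, from 4.97e-09). Klra17, a lectin-like receptor gene, had 0 reads in DKO against 213 ± 128 CPM and was at least 1350-fold lower. Colq and Nccrp1, with 0 reads in ex-cDC1, reached 55.3 ± 42.6 and 112 ± 66.0 CPM and were at least 265-fold and 587-fold higher. The MHC class II gene H2-Eb1 rose from 790 ± 119 to 2250 ± 500 CPM (log2 fold change 1.51 ± 0.30, edgeR adjusted p = 0.00432). Of 27 migratory genes 2 rose, 0 fell and 25 did not pass (5 rose and 0 fell adjusted over the list alone, camera adjusted p = 3.6e-06). Of 14 genes for MHC class II presentation, 3 rose, 0 fell and 11 did not pass (5 rose and 0 fell adjusted over the list alone, camera adjusted p = 0.0193, adjusted p = 0.311 with an estimated correlation). Stroma and endothelium markers averaged 0.111 CPM against 10.5 (camera adjusted p = 0.0245, adjusted p = 0.311 with an estimated correlation), and granulocyte markers 8.15 against 1.99 CPM (camera adjusted p = 0.02, adjusted p = 0.311 with an estimated correlation). The count of 414 changed genes, 208 higher and 206 lower, was 225, 193 and 167 without ex-cDC1 replicate 1, 2 and 3, 42 with only the 6 libraries (31 of them higher) and 1580 by DESeq2.

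Compared with cDC1 wt, DKO had 1509 changed genes, 723 higher and 786 lower. This was 676 without the 12 Irf4-floxed libraries, 186 with only the 6 libraries and 2790 by DESeq2. Clec9a and Cadm1 had 0 reads in DKO against 218 ± 53.9 and 142 ± 69.8 CPM, at least 1500-fold and 1080-fold lower. Xcr1 fell by 6.33 ± 0.81 on the log2 scale (edgeR adjusted p = 1.22e-05). Gpr183 rose from 5.18 ± 1.05 to 647 ± 268 CPM (log2 fold change 6.95 ± 0.73, edgeR adjusted p = 1.23e-07). The gap junction gene Gjb2 and the ubiquitin ligase gene Rnf43, with 0 reads in cDC1 wt, were at least 702-fold and 398-fold higher. The Notch ligand Dll4 averaged 34.0 ± 13.5 CPM against 0 reads. Of 20 cDC1 core genes 12 fell, 1 rose and 7 did not pass (3 rose and 14 fell adjusted over the list alone, camera adjusted p = 2.04e-07). Of 14 genes for MHC class II presentation 7 rose, 1 fell and 6 did not pass (8 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.000694, adjusted p = 0.251 with an estimated correlation), with H2-Eb1 at 2250 ± 500 against 301 ± 145 CPM (edgeR adjusted p = 1.69e-07). Stroma markers averaged 0.111 against 166 CPM, and Col1a1 0.0882 ± 0.0768 against 879 ± 1260 CPM (camera adjusted p = 0.00144, adjusted p = 0.251 with an estimated correlation). Irf4 rose and Irf8 fell by the same test (log2 fold change 2.22 ± 0.73 and -1.58 ± 0.46, edgeR adjusted p = 0.0452 and 0.0241, with ranges over processing settings of 2.55e-05 to 0.0947 and 0.00265 to 0.262). The Irf4 call was lost without cDC1 wt replicate 1 or 3 (0.151 and 0.0969) or DKO replicate 1 or 2 (0.165 and 0.054), and the Irf8 call without cDC1 wt replicate 2 or 3 (0.0631 and 0.056) or DKO replicate 2 or 3 (0.0727 and 0.101).

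In the Irf4 arm, cDC1 labelled Irf4 knockout were compared with controls within each labelled gate. Irf4 fell in the libraries labelled migratory Irf4 knockout (log2 fold change -2.58 ± 0.74, edgeR adjusted p = 0.0222). The call was lost without migratory Irf4 knockout replicate 1, 2 or 3 (0.111, 0.0696 and 0.0685) and without migratory control replicate 1 or 3 (0.0567 and 0.0672). Irf8 rose from 164 ± 32.4 to 575 ± 64.1 CPM (edgeR adjusted p = 0.00793, and 0.0568 without migratory control replicate 2). In the libraries labelled resident, Irf4 averaged 12.9 in knockout and 26.9 CPM in control (log2 fold change -1.11 ± 0.72, edgeR adjusted p = 0.404), a difference that became 0.25 without resident control replicate 1. Irf8 rose there from 152 ± 38.6 to 601 ± 85.0 CPM (log2 fold change 1.98 ± 0.47, edgeR adjusted p = 0.00358). Xcr1 averaged 1970 ± 376 and 1880 ± 339 CPM in the labelled migratory and resident Irf4 knockout, against 244 ± 78.7 and 248 ± 113 in the controls. Each comparison had 1251 changed genes, 395 higher and 856 lower for the labelled migratory gate and 376 higher and 875 lower for the resident gate. Library composition went with genotype as labelled. Malat1 took 8.77 and 8.45% of counts in the labelled migratory and resident Irf4 knockouts against 25.2 and 27.8% in the controls. TMM factors were 1.205 to 1.303 against 0.79 to 1.1. The counts were 1246 and 1253 without Malat1. Fitting only the 6 libraries gave 2337 and 2586, and DESeq2 gave 1923 in the migratory gate. The median log2 fold change of all genes was 0.107 and 0.115, which is above 0.

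Genes of the migratory and maturation program fell in both labelled gates. Of 27, 24 fell, 1 rose and 2 did not pass in each gate, with the same numbers adjusted over the list alone (camera adjusted p = 1.24e-32 and 1.54e-33). The chemokine receptor Ccr7, which directs migration to lymph nodes, averaged 3.94 ± 4.68 CPM in the libraries labelled migratory Irf4 knockout, 819 ± 65.2 in migratory control, 1.76 ± 0.297 in resident Irf4 knockout and 810 ± 112 in resident control. The actin-bundling gene Fscn1 fell in the labelled migratory gate (log2 fold change -10.58 ± 0.56, edgeR adjusted p = 1.93e-15) and in the resident gate (-10.02 ± 0.54, edgeR adjusted p = 3.31e-15). The surface protein gene Tmem123 averaged 174 ± 47.0 against 10700 ± 910 CPM and 172 ± 8.98 against 11000 ± 1000 CPM. As labelled, the resident control libraries therefore held the program at the level of the migratory control libraries, and the migratory Irf4 knockout libraries at the level of the resident Irf4 knockout libraries.

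**Figure D4:**
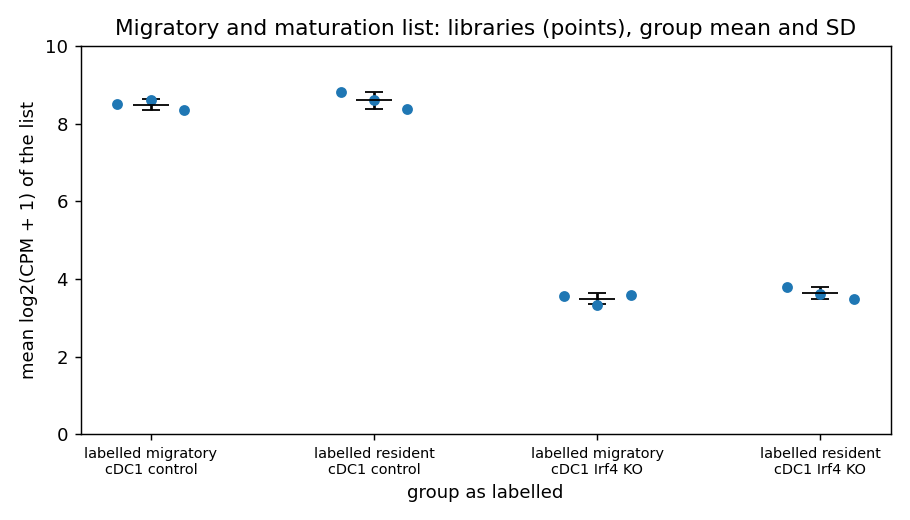
Mean log2 (CPM + 1) of 27 migratory and maturation genes in the 4 groups of the Irf4 arm as labelled, with each point a library and lines at the mean and SD of n = 3. Both control groups lay at 8.49 ± 0.14 (migratory) and 8.60 ± 0.22 (resident) and both knockout groups at 3.49 ± 0.14 and 3.63 ± 0.16.

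Several other lists moved in both labelled gates, given as migratory then resident. The labels of this arm are in doubt, as weighed below. These changes, and those of Irf8 and Xcr1 above, therefore cannot be assigned to Irf4 genotype rather than to the gate. Of 20 cDC1 core genes 13 rose, 1 fell and 6 did not pass in each (17 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.69e-17 and 3.04e-17), with Ppt1 at 3130 ± 388 against 242 ± 90 CPM and 3420 ± 469 against 291 ± 88.8 CPM. Of 14 genes for MHC class II presentation 10 and 9 rose and 2 fell in each (11 rose and 2 fell adjusted over the list alone, camera adjusted p = 1.07e-05 and 4.58e-06), including H2-Ab1 (log2 fold change 2.92 ± 0.30 and 3.03 ± 0.30, edgeR adjusted p = 6.31e-09 and 3.53e-09). Of 16 genes for MHC class I presentation 6 and 7 fell and 1 and 0 rose (8 and 9 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00019 and 3.8e-05, adjusted p = 0.0758 with an estimated correlation in the migratory gate), including H2-K1 at 915 ± 59.2 against 4210 ± 804 CPM and 913 ± 111 against 4640 ± 333 CPM. Of 15 cholesterol synthesis genes 8 and 9 fell and 0 rose (8 and 10 fell adjusted over the list alone, camera adjusted p = 4.48e-07 and 1.36e-08), including Idi1 (log2 fold change -4.90 ± 0.35 and -4.79 ± 0.35, edgeR adjusted p = 2.82e-12 and 3.69e-12). Of 17 proliferation genes 4 and 8 rose and 0 fell (11 and 14 rose adjusted over the list alone, camera adjusted p = 1.55e-07 and 1.36e-08), including the cycling marker Mki67 at 1360 ± 78.4 against 373 ± 56.1 CPM and 1040 ± 285 against 278 ± 34.0 CPM. Of 18 cytokine and co-signal genes 7 fell and 1 rose in each (7 and 10 fell and 2 rose adjusted over the list alone, camera adjusted p = 8.1e-05 and 2.41e-06), including the interleukin receptor gene Il15ra at 5.49 ± 3.85 against 278 ± 81.9 CPM and 11.7 ± 2.48 against 287 ± 78.1 CPM. Of 13 genes of the unfolded protein response 2 and 3 rose (3 rose adjusted over the list alone in each, camera adjusted p = 0.0189 and 0.0267), including the chaperone Hspa5 at 803 ± 98.8 against 201 ± 22.6 CPM and 997 ± 153 against 209 ± 60.0 CPM.

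The difference between the labelled gates was tested directly. For the controls, edgeR called 0 genes between the libraries labelled migratory and resident, with 326 at an unadjusted p under 0.05 (623 by chance), and DESeq2 called 53. Irf4 averaged 173 ± 53.7 against 26.9 ± 29 CPM (log2 fold change 2.65 ± 0.75, edgeR adjusted p = 1). It passed by DESeq2 (0.0309) and without the filter on low counts (6.99e-05, in a range of 6.99e-05 to 1 over the alternatives). For a change of the Irf4 genotype effect with the gate, edgeR called only H2-M2, an MHC class I-like gene (log2 difference 5.85 ± 0.90, edgeR adjusted p = 0.0038). It averaged 6.25 ± 4.19 CPM in labelled migratory Irf4 knockout, 346 ± 107 in migratory control, 0.0721 ± 0.0719 in resident Irf4 knockout and 277 ± 2.71 in resident control. The call was lost without resident Irf4 knockout replicate 2 (0.0693) and with only the 12 Irf4-floxed libraries (0.0643), the highest over the processing settings, from 5.43e-09, and DESeq2 called 56 genes. The H2-M2 difference rests on low levels in both knockouts. In simulated counts this test recovered 2% of 8-fold changes, and 1 of its 3 calls was false, so an effect of the gate on other genes is not excluded.

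The effect of Irf4 genotype in DKO against ex-cDC1 was set against that in the labelled migratory gate, to ask whether it depends on Irf8. In all, 1318 genes differed, 867 with a higher and 451 with a lower effect in the Irf8-floxed cells, and DESeq2 called 2007. Of 27 migratory genes 23 had a higher effect and 0 a lower one (24 and 0 adjusted over the list alone, camera adjusted p = 4.87e-42). Tmem123 averaged 7680 ± 1910 CPM in DKO and 9370 ± 1450 in ex-cDC1, against 174 and 10700 CPM in the labelled migratory Irf4 knockout and control (log2 difference 5.65 ± 0.29, edgeR adjusted p = 4.75e-15). The Myc antagonist Mxd1 averaged 7570 ± 822 CPM in DKO and 3260 ± 172 in ex-cDC1 (log2 difference 6.15 ± 0.26, edgeR adjusted p = 2.02e-17). The chemokine Ccl22 averaged 2540 ± 1010 CPM in DKO and 1250 ± 121 in ex-cDC1 (log2 difference 10.35 ± 0.57, edgeR adjusted p = 1.37e-14). Of 15 cholesterol synthesis genes 7 had a higher effect and 0 a lower one (8 and 0 adjusted over the list alone, camera adjusted p = 2.35e-07). Of 20 cDC1 core genes 9 had a lower and 1 a higher effect (11 and 2 adjusted over the list alone, camera adjusted p = 7.01e-05). These differences rest on the libraries labelled migratory Irf4 knockout, whose migratory genes stood at the resident knockout level, and on DKO libraries that held 483 ± 291 CPM of Irf4. With the libraries labelled resident control in place of those labelled migratory Irf4 knockout, a comparison chosen after the values were seen, 29 genes differed. The log2 difference of Tmem123 was then -0.33 ± 0.27 (edgeR adjusted p = 0.642) and that of Irf4 3.53 ± 1.02 (edgeR adjusted p = 0.14). That of Irf8 was 3.03 ± 0.66 (edgeR adjusted p = 0.0405), against 1.11 with the labels as deposited. With the labels as deposited, Irf4 differed by 3.46 ± 1.02 (edgeR adjusted p = 0.0271), a call lost without migratory Irf4 knockout replicate 1 or 2 (0.0714 and 0.0508), migratory control replicate 1 or 3 (0.0542 and 0.057), ex-cDC1 replicate 1 (0.0676) or DKO replicate 1 (0.0821).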

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

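The tests of the 3 patterns weighed here and the values with exchanged labels were chosen only after the results were seen, while the interactions and the comparisons of sample splits were planned. Both interactions drew attention because an effect of Irf4 genotype differed between groups. Between the labelled gates it differed for 1 gene, H2-M2, by 5.85 on the log2 scale. Between Irf8-floxed cells and the labelled migratory gate it differed for 1318 genes, among them the Myc antagonist Mxd1 (6.15), Tmem123 (5.65), the actin-bundling gene Fscn1 (11.79), the chemokine Ccl22 (10.35), the bicarbonate transporter Slc4a8 (7.65) and the guidance gene Sema6d (8.71). Slc4a8 averaged 1420 ± 373 CPM in DKO and 1720 ± 350 in ex-cDC1, and Sema6d 702 ± 45.1 and 729 ± 64.5 CPM. These differences rest on the labels of the Irf4 arm, which are weighed below. With the labels of the migratory Irf4 knockout and resident control exchanged, 29 genes differed (22 of them also as deposited, in the same direction). Mxd1 then differed by 1.21 ± 0.24 and Irf8 by 3.03 ± 0.66 (edgeR adjusted p = 0.0173 and 0.0405), and Tmem123 (-0.33), Fscn1 (0.99), Ccl22 (0.87), Slc4a8 (-0.45) and Sema6d (-0.27) did not pass. The difference for H2-M2 is the same sum of groups either way.

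Single libraries far from their group were not tested in these groups of 3. For the interaction with the gate, 2 of 30 drawn splits gave as many genes as the real 1, the real split and 1 that called 658 genes, and the others gave 0. By this count chance was not excluded, and the split with 658 genes points to a structure of the samples. It kept both labelled migratory groups whole and mixed the resident ones, so the structure is the labelled difference between the migratory groups. For the interaction with Irf8, 1 of 30 splits, the real one, gave as many as 1318, and the highest other gave 975. The 3 others that kept both labelled migratory groups whole gave 931 to 975 genes, and those that mixed them gave 0 to 12. The count was therefore set by the labelled migratory groups, and whether chance accounts for a dependence on Irf8 cannot be told from these splits. For comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05. The real split was the 1 with most genes in ex-cDC1 against cDC1 wt (464, highest other 2), cDC2 wt against cDC1 wt (507 and 3), ex-cDC1 against cDC2 wt (3 and 0), ex-cDC1 against cDC2 flox (4 and 1), DKO against ex-cDC1 (414 and 10), DKO against cDC1 wt (1509 and 75), and the labelled migratory (1251 and 2) and resident (1251 and 0) Irf4 knockouts. In cDC2 flox against cDC2 wt 2 splits gave at least the real 1 (highest other 1), and in labelled migratory against resident control all 10 gave 0.

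In the Irf4 arm, genes of the migratory program such as Ccr7 and Fscn1 were at the migratory control level in the libraries labelled resident control and near 0 in those labelled migratory Irf4 knockout. Correct labels and gates that separated the cells, with a loss of the program in Irf4 knockout cells, would need a lower program in resident control, whose list mean lay 0.11 log2 above migratory control. A minority of migratory cells in the resident control sort is argued against by list genes at a median of 106.6% of the migratory control level. An exchange of the labels of both groups stays open. In the list 6 of 6 libraries lay nearer to the group of the other gate, which restates the pattern and is no test of it. Outside the list, same-numbered libraries of both gates correlated at a mean of 0.074 as labelled and 0.047 with the labels exchanged (-0.057 to 0.148 and -0.026 to 0.131), which does not decide. As labelled, the control pairs stood at 0.101, 0.148 and 0.105 and the knockout pairs at 0.102, 0.048 and -0.057. Under an exchange, pairs of the labelled migratory groups stood at 0.089, -0.026 and -0.014 and those of the labelled resident groups at 0.069, 0.131 and 0.034. The Y-linked gene Ddx3y was at 0 and 0.474 CPM in replicate 3 of labelled migratory control and migratory Irf4 knockout, against 75.4 and 69.9 CPM in replicate 3 of resident control and resident Irf4 knockout. In replicates 1 and 2 it was at 82.2 and 77.8 CPM in labelled migratory control and 71.6 and 63.5 CPM in resident control. In migratory Irf4 knockout it was at 26.1 and 33 CPM, and in resident Irf4 knockout at 45.4 and 29.4 CPM. Replicates 1 and 2 thus paired more closely as labelled than under an exchange. The replicate 3 values go with an exchange only if equal numbers mean the same animals, which the labels do not state. Gates that did not separate the cells, with a loss of the program in both labelled Irf4 knockouts, cannot be told apart from an exchange either. Irf4 in labelled resident control was 15.5% of that in migratory control, which such gates would not give. The call, however, depended on the tool (adjusted p = 1 by edgeR, 0.0309 by DESeq2) and on the filter, since it passed by edgeR without the filter on low counts. Whether Irf4 loss changes the migratory program, or the other lists that moved in this arm, within a gate stays open.

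In ex-cDC1, cDC1-high genes stood at the cDC2 wt level while cDC2-high genes lay between both lineages. A mixture of unchanged cDC1 and cDC2 needs the same cDC1 share from both gene sets, but the shares differed by 50.2 ± 7.9 percentage points (41.8 to 57.4 over 3 libraries), against at most 26.6 in mixtures made from wild-type libraries. The shares and the made mixtures both took cDC2 wt as sorted for the cDC2 part. They therefore cannot weigh against cDC2 that lack other transcripts of that sort. Monocyte and macrophage transcripts in the CD11b-positive sorts that the reporter-positive sort lacks cannot be told apart from a lineage difference. The 7 such genes weighed were picked because they were higher in cDC2 wt than in cDC1 wt, so that direction is no observation. In ex-cDC1 they lay at a median of -8.9% of the way from cDC1 wt to cDC2 wt, which either explanation allows. A partial conversion of cDC1 after loss of Irf8 is the biological explanation the design names, and it stays a hypothesis beside the open one.

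The DKO libraries held Irf4 and Irf8 counts although both genes were floxed. Unchanged cDC1 that kept both genes are argued against for Irf4, which stood at 466% of the cDC1 wt level. They are argued against as the source of all Irf8 counts too, since they would have to make up at least 14.1 to 49.7% of the 3 libraries and bring their abundant transcripts. Of 109 cDC1-high genes with at least 50 CPM in each cDC1 wt library, 13 lay below 50% of the level so required in all 3 DKO libraries, among them Clec9a and Cadm1 with 0 reads. In single DKO libraries 17 to 36 genes did, against 2 to 10 in each cDC1 wt library set against the other 2. Other cells that kept both genes were not weighed. In cDC2 wt, Irf8 averaged 42.7 ± 15.7 and Irf4 155 ± 34.8 CPM, against 77.5 ± 49.3 and 483 ± 291 CPM in DKO. Irf8 in DKO lay 18.4 ± 26.1% of the way from cDC2 wt to cDC1 wt. Transcript from exons that the deletion leaves (483 CPM of Irf4 over the whole gene) could not be separated with whole-gene counts. By the same counts, Irf4 averaged 28.8 and 12.9 CPM in the labelled migratory and resident Irf4 knockouts, against 173 and 26.9 CPM in their controls. Those levels are lower than in DKO. The labels of that arm are in doubt and its cells had no floxed Irf8, so they do not settle the point. A batch or strain difference could not be separated from genotype either, with the ribosomal entry Rn45s at 1.38% of counts in DKO against group means of 0.34 to 0.691% elsewhere. Such a difference and transcript from the exons left may both contribute.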

How the results depend on the processing

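The model without the 12 Irf4-floxed libraries, the lineage count from 2 groups fitted alone and every value of the 3 added comparisons (resident against migratory Irf4 knockout, DKO against cDC2 wt, and labelled migratory control against cDC1 wt) were chosen after the data were seen. Gene counts stayed within 1.5 times the reported ones with RLE size factors, only called genes with a log2 fold change of at least 1 in size, at least 10 CPM in 3 libraries, and without Malat1, and 395 of 396 named gene results kept their call with RLE size factors.

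DESeq2 called 1379 genes in ex-cDC1 against cDC1 wt, 1407 in cDC2 wt against cDC1 wt, 277 in ex-cDC1 against cDC2 wt, 225 in ex-cDC1 against cDC2 flox, 80 in cDC2 flox against cDC2 wt, 1580 in DKO against ex-cDC1, 2790 in DKO against cDC1 wt, 1923 in the labelled migratory Irf4 knockout, 56 and 2007 in the interactions with gate and Irf8, 53 in labelled migratory against resident control, and 41, 1745 and 691 in the added comparisons. Without the filter on low counts the numbers were 857, 861, 130, 104, 12 and 824 in the first 6 of these, 7 in the interaction with gate, 8 in migratory against resident control, and 17, 925 and 413 in the added comparisons. With only the groups compared, they were 122, 111, 0 (ex-cDC1 against cDC2 wt), 0 (cDC2 flox against cDC2 wt), 42 (DKO against ex-cDC1), 186 (DKO against cDC1 wt), 2337 and 2586 (labelled migratory and resident Irf4 knockout), 0 (interaction with gate), and 0, 43 and 6 in the added comparisons. Without the 12 Irf4-floxed libraries they were 191, 215, 0, 0, 0, 128 and 676 in the first 7, and 174 in DKO against cDC2 wt. Replicates correlated at 0.850 to 0.879 in cDC1 wt and 0.857 to 0.872 in DKO, against 0.933 to 0.971 in the Irf4 arm. The reported p-values use a spread per gene shared over all groups. They can therefore be too small where cDC1 wt or DKO is compared and too large in the Irf4 arm. The cause of the changed counts was not tested.

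With 1 library left out, counts ranged from 255 to 558 in ex-cDC1 against cDC1 wt, 227 to 577 in cDC2 wt against cDC1 wt, 1 to 7 in ex-cDC1 against cDC2 wt, 0 to 8 in ex-cDC1 against cDC2 flox, 0 to 3 in cDC2 flox against cDC2 wt, 167 to 498 in DKO against ex-cDC1, 1086 to 1495 in DKO against cDC1 wt, 879 to 1013 and 878 to 987 in the labelled migratory and resident Irf4 knockout, 0 to 1 and 918 to 1326 in the interactions with gate and Irf8, and 0 to 0 in migratory against resident control. In the added comparisons they ranged from 1 to 4, 227 to 635 and 9 to 211. Lineage counts ranged from 48 to 64 (cDC1-high) and 39 to 59 (cDC2-high), and positions from 67.8 to 76.4% for ex-cDC1 and 77.5 to 81.3% for DKO. Of single genes, 3 changed direction: Pdia4 in DKO against cDC1 wt (-3.51 to 0.19, the latter without cDC1 wt replicate 2), Irf4 in the resident Irf4 knockout (-2.12 to 0.25, the latter without resident control replicate 1) and Irf8 in resident against migratory Irf4 knockout (-0.07 to 0.14, with -0.03 without migratory Irf4 knockout replicate 1 and -0.07 without resident Irf4 knockout replicate 2). Over 2442 such gene fits, 1832 kept their call, 603 lost it and 3 gained it. Over 2954 gene fits with other settings, 2682 kept it, 265 lost it and 7 gained it. The losses were uneven over the settings. With only the groups compared, 125 calls were lost and 240 kept. Without the 12 Irf4-floxed libraries 89 were lost and 137 kept, and with a replicate block 44 were lost and 352 kept.

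No pairing by replicate number was assumed. Over all genes of at least 10 CPM, with group means taken off, same-numbered libraries correlated at -0.054 to 0.133, in no comparison above 0.1 for every pair. Outside the migratory list and on another log scale, same-numbered libraries of labelled migratory and resident control correlated at 0.101, 0.148 and 0.105. Each library correlated best with its own number in cDC2 wt against cDC1 wt, cDC2 flox against cDC2 wt and labelled migratory against resident control, a hint from the data and not the design. A replicate block gave 5 genes in ex-cDC1 against cDC2 wt and 9 in ex-cDC1 against cDC2 flox, kept the other counts within 1.5 times, and gave 61 list calls against 60. With an estimated correlation, 40 list calls were left.

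The cDC1-high genes that fell in ex-cDC1 numbered 39 at a log2 fold change of at least 2, a smaller set, and 40 with ex-cDC1 and cDC1 wt fitted alone, where 20 cDC2-high genes rose. With lineage genes from cDC2 wt the position was 57.8% for ex-cDC1 and 64.5% for DKO, and with genes of at least 10 CPM 86.5% for DKO, and the cause was not tested. Shares of cDC1 wt regions in ex-cDC1 and cDC2 flox, then of cDC2 wt regions, were 45.9, 42, 78.0 and 78.8% at a reciprocal overlap of 50%, and 20.2, 16.5, 71.9 and 77.1% with equally long lists. Above the median signal they were 42.3% (cDC1 wt regions in cDC2 flox), 91.5 and 94.1% (cDC2 wt regions). The odds ratio of gained regions at genes that fell was 0.952 within 2 kb and 1.27 (adjusted p = 0.141, in a range of 0.0216 to 1) with equally long lists. For lost regions at genes that rose it was 2.03 within 2 kb, 1.03 within 50 kb and 1.19 with equally long lists, against 0.876, none past the threshold, and the cause was not tested. In simulated data at most 2% of 1.5-fold changes were recovered, and whether more depth or more libraries would recover them was not tested.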

Other observations

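The 3 gene comparisons given here were added after values were seen, and the test of the hypothesis on open regions was planned. Set against cDC2 wt, DKO had 589 changed genes, 271 higher and 318 lower. The chemokine receptor Ccr2, which draws cells to inflamed tissue, averaged 1.68 ± 0.967 against 205 ± 23.7 CPM (log2 fold change -6.92 ± 0.97, edgeR adjusted p = 0.000133). The lectin gene Cd209a averaged 0.189 ± 0.167 against 53.1 ± 7.73 CPM (edgeR adjusted p = 0.0149), and Klra17 had 0 reads in DKO and was at least 679-fold lower. H2-Eb1, Ccl22 and Fscn1 rose by 1.54 ± 0.30, 1.74 ± 0.34 and 1.72 ± 0.36 on the log2 scale (edgeR adjusted p = 0.00289, 0.00327 and 0.0061). Of 27 migratory genes 5 rose, 0 fell and 22 did not pass (16 rose and 0 fell adjusted over the list alone, camera adjusted p = 1.55e-14). Of 19 cDC2 core genes 5 fell, 0 rose and 14 did not pass (0 rose and 9 fell adjusted over the list alone, camera adjusted p = 9.79e-06, adjusted p = 0.0715 with an estimated correlation). The gene count was 319, 227 and 320 without cDC2 wt replicate 1, 2 and 3, 174 without the 12 Irf4-floxed libraries, 43 with only the 6 libraries (34 of them higher), 925 without the filter on low counts and 1745 by DESeq2.

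The controls of both arms differed as well. The libraries labelled migratory control had 125 genes changed against cDC1 wt, 27 higher and 98 lower. Xist averaged 9590 ± 1030 against 104 ± 138 CPM, and 5590 ± 1410 to 9590 ± 1030 CPM over the 4 groups of the Irf4 arm. The Y-linked gene Ddx3y averaged 53.3 ± 46.2 against 191 ± 64.7 CPM and 19.9 ± 17.1 to 70.2 ± 6.11 CPM over those 4 groups. Both transcripts were therefore found together in the libraries of the Irf4 arm, except in replicate 3 of labelled migratory control (Ddx3y at 0) and migratory Irf4 knockout (0.474 CPM). The matrix genes Col1a1 and Fn1 were lower in labelled migratory control, with Col1a1 at 0.156 ± 0.135 against 879 ± 1260 CPM and Fn1 at 0 reads against 143 ± 114 CPM, at least 797-fold lower. That count was 9, 66 and 34 without migratory control replicate 1, 2 and 3, 72 and 211 without cDC1 wt replicate 1 and 3, 6 with only the 6 libraries, 413 without the filter on low counts and 691 by DESeq2. Between resident and migratory Irf4 knockout libraries, edgeR called H2-M2 (log2 fold change -6.17 ± 0.75, adjusted p = 3.41e-05) and the cyclase gene Adcy6 (-3.30 ± 0.57, adjusted p = 0.015), both named after their values were seen. That count was 1 without migratory Irf4 knockout replicate 1 or resident Irf4 knockout replicate 2, 4 without migratory Irf4 knockout replicate 2, 0 with only the 6 libraries, 17 without the filter on low counts and 41 by DESeq2.

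A hypothesis planned before the data were examined held that cDC2-high genes in ex-cDC1 are open further than their expression rose. Of 588 regions near cDC2-high genes called in cDC2 wt and not in cDC1 wt, 82.8% (95% interval 79.6 to 85.7) were called in ex-cDC1 and 84.0% in cDC2 flox, so the ex-cDC1 share was 98.6% of the cDC2 flox share. Expression of those genes in ex-cDC1 had moved 49.8 ± 17.0% of the way to cDC2 wt. Near cDC1-high genes, 37.4% (31.4 to 43.9) of 227 regions called in cDC1 wt and not in cDC2 wt were called in ex-cDC1 and 31.3% in cDC2 flox, while those genes' expression had moved 97.6 ± 2.8% of the way. Mgl2 and Cd209a, with 2 and 3 regions called in ex-cDC1 against 3 and 2 in cDC2 wt, averaged 0.0982 and 4.65 CPM against 10.8 and 53.1. Regions called in cDC2 wt and not in cDC1 wt were, however, called in ex-cDC1 at much the same rate near cDC1-high genes (80.5%, 75.8 to 84.5) and among all such regions (83.6%). The share near cDC2-high genes therefore says nothing particular about those genes, list length goes with genotype and called regions carry no level, so the hypothesis stays open.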
